A study of Orbicella faveolata with 56 samples.

How the data were processed

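The measurements are RNA sequencing libraries from fragments of the Caribbean reef coral Orbicella faveolata, a colonial animal that houses single-celled algal symbionts in its tissue. Per the labels, 14 corals collected at inshore or offshore reefs of the Florida Keys were each split into 4 fragments, which were placed at an inshore or an offshore transplant site and then kept at 30 or 32 °C. Temperatures were changed over 7 days and held for 6 days before sampling. The 8 inshore-origin corals carried 6 genotype labels, because corals A3, A5 and A6 share genotype In1, and the 6 offshore-origin corals carried 6. All offshore-origin corals came from a single collection site, so origin cannot be separated from that site.

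RNA was extracted with a column kit and stranded mRNA libraries were prepared, per the labels' protocols. Trimmomatic 0.36 and RSEM are named in the submitters' processing notes, and the tables themselves are named for kallisto. The version of the quantifier and the assembly used as reference are not given in the sources used here. Both tables hold estimated counts per isoform, deposited by the authors without normalization: 87440 rows for a table taken here as the host and 52359 rows for a table named for Durusdinium trenchii, a dinoflagellate symbiont. Of the values, 74.7% were whole numbers among host rows and 99.3% among symbiont rows. Values were rounded to whole numbers before any count test. Every gene part of an identifier had exactly 1 isoform row, so summing isoforms per gene changed nothing, and the isoform level was not run as an alternative because it is identical.

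Each table has 56 columns. One column (1 in each table) matched no label, since its name gives the low temperature where the only unmatched label, coral C3 of offshore origin at the inshore site, gives 32 °C. It was not used, which leaves 55 libraries and 5 of them in the group of offshore-origin corals at the inshore site at 32 °C. The files do not pair identifiers with gene names, so the gene lists fixed for chaperones, antioxidant enzymes, photosystems and other functions were not tested. The text instead names the 2 identifiers that rose most and the 2 that fell most per comparison, among those with adjusted p under 0.05, a mean log2 CPM of at least 1 and, outside interactions and origin, the same direction in at least 75% of coral pairs. CPM, computed here, scales counts by the TMM-adjusted total of the rows that entered the fit. Symbiont CPM are therefore not shares of the whole symbiont table, and in the fit over all corals they are scaled to 288 rows.

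Host totals ran from 2850075 to 7239229 counts per library with a median of 5021488. Symbiont totals ran from 2865 to 1801987 with a median of 23234, so most symbiont rows could be tested in few libraries. Binomial 95% Wilson intervals of shares cover counting error only. No pair of libraries of a group agreed within sampling noise, the lowest chi-square per degree of freedom being 4.00 (genes with at least 20 counts in the pair). A library was said to stand apart where its mean correlation with the others lay over 3 median absolute deviations below the median, which held for 7 libraries.

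Count tests used edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr on the 8 groups with a minimum count of 10, and the quasi-likelihood F test, with Benjamini-Hochberg adjustment at 0.05. One fit per table held coral as a block and, within each origin, the 3 conditions beside the inshore site at 30 °C, with 35 residual degrees of freedom. Coral was a block because the fragments of a coral are the same animal. Same-coral libraries deviated together from their group means, with mean correlations between 0.402 and 0.772 over the 14 corals. Heat effects were averaged with equal weight over the 4 combinations of origin and transplant site. Origin was tested on counts summed per genotype, 6 against 6. The symbiont share was the symbiont total over both totals, and it was tested as the log2 ratio of symbiont to host counts by exact sign-flip tests over corals or exact permutation over the 12 genotypes, two-sided. The size of the heat response was the slope of a genotype's log2 changes (CPM plus a prior count of 2) on the mean change of the other genotypes. The baseline test took genes raised by heat in offshore-origin corals at the offshore site and compared their levels at 30 °C at the inshore site between origins, so that list and baseline share no library.

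These designs, the rule for named identifiers and most alternatives were fixed before the data were examined: RLE size factors, the DESeq2 1.42.0 Wald test, no low-count filter, no replicate block, In1 corals summed, each coral left out in turn, and 2 treatments of library numbers, since numbers 1 to 16 are all at 30 °C. Alternatives added after the data were seen left out the libraries that stand apart or the host rows that go with the symbiont ratio (absolute r over 0.7 within groups), added that ratio as a term, left out each coral from the tests of the share, or took the symbiont heat effect in offshore-origin corals at the inshore site alone, with and without a term for library number. DESeq2 was run without the low-count filter, over 82742 host rows (81332 for origin), so test and filter change together wherever its counts are given. Other splits of the samples, drawn at random with the real one included, numbered 40 per within-coral comparison and 60 for origin. In the within-coral splits the dispersion trend was held at its value for the real grouping and the quasi-likelihood spread was estimated anew.

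The functions were tested on simulated data drawn from the real means and totals, with 200 changed genes. All fragments of a coral had the same pooled composition, and for origin all genotypes did, so no site change in composition was simulated. For host genes at 32 against 30 °C, 35733 genes were tested, and 56.2% of 1.5-fold, 87.9% of 2-fold and 98.4% of 4-fold changes were recovered, with 7 unchanged genes called. In single combinations of origin and site the recovery of 2-fold changes lay between 24.2 and 40.9%. For host origin, 41009 genes were tested, and 6.56% of 2-fold, 66.7% of 4-fold and 96.6% of 8-fold changes were recovered. For symbiont heat over all corals, 488 rows were tested, and few changed rows were among them. Of these, 0 of 5 changes of 1.5-fold and 7 of 7 of 4-fold were recovered, and 0 rows changed 2-fold could be tested. In single combinations 4-fold changes were recovered in 0 to 4 of 7 rows, and in 0 of 7 at the offshore site for either origin.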

Results

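Gene expression was measured in 55 libraries of O. faveolata fragments that had been transplanted to an inshore or an offshore site and then held at 30 or 32 °C. Inshore-origin corals gave 8 libraries in each of their 4 conditions. Offshore-origin corals gave 6 in each, except 5 at the inshore site at 32 °C. The title of the study puts its question as the heat tolerance of corals from different transplant sites. Host totals per library lay between 2850075 and 7239229 estimated counts, and symbiont totals between 2865 and 1801987.

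Host libraries of a genotype were more alike than libraries of different genotypes. The median correlation of log2 levels across 20420 genes, which are not independent replicates, was 0.951 between libraries of a coral and 0.856 between genotypes. The most similar library came from the same coral for 49 of 55 libraries and from the same genotype for 54. The exception was coral C3 at the offshore site at 30 °C, which is among the 7 libraries that stand apart from the rest.

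The first comparison asked which host genes respond to 32 °C. At 32 °C 640 genes were higher and 500 lower than at 30 °C, out of 35219 tested (edgeR quasi-likelihood test, coral as block). Most changes were small: the median rise was 1.37-fold and the median fall 1.44-fold, and 72 rising and 75 falling genes changed over 2-fold. OFAVBQ_DN218234_c4_g1 rose 6.52-fold (log2 2.70 ± 0.437 SE, adjusted p = 0.000178, edgeR), in 23 of 27 coral pairs. Its level in inshore-origin corals at the inshore site went from 5.63 ± 6.28 CPM (SD, n = 8) to 32.3 ± 37.5. OFAVBQ_DN224748_c2_g1 rose 4.31-fold in 25 of 27 pairs, from 3.66 ± 1.83 to 27.7 ± 33.3 CPM in the same corals (SD, n = 8). OFAVBQ_DN198750_c0_g1 fell 5.30-fold in 22 pairs and OFAVBQ_DN223145_c3_g1 fell 3.33-fold in 23 pairs (edgeR adjusted p = 0.0117 and 0.0122). The files pair none of these identifiers with a gene name. The fit without the coral block called 321 genes, a term for library numbers 1 to 16 beside the block gave 261 (145 of the 640 and 88 of the 500 among them), and libraries numbered 17 to 56 alone, which hold only 1 offshore-origin coral at the inshore site at 30 °C, gave 50. Leaving out B2, C2, C4 or C6 gave 724, 738, 666 or 655, and leaving out the 7 libraries that stand apart gave 1751.

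**Figure D1:**
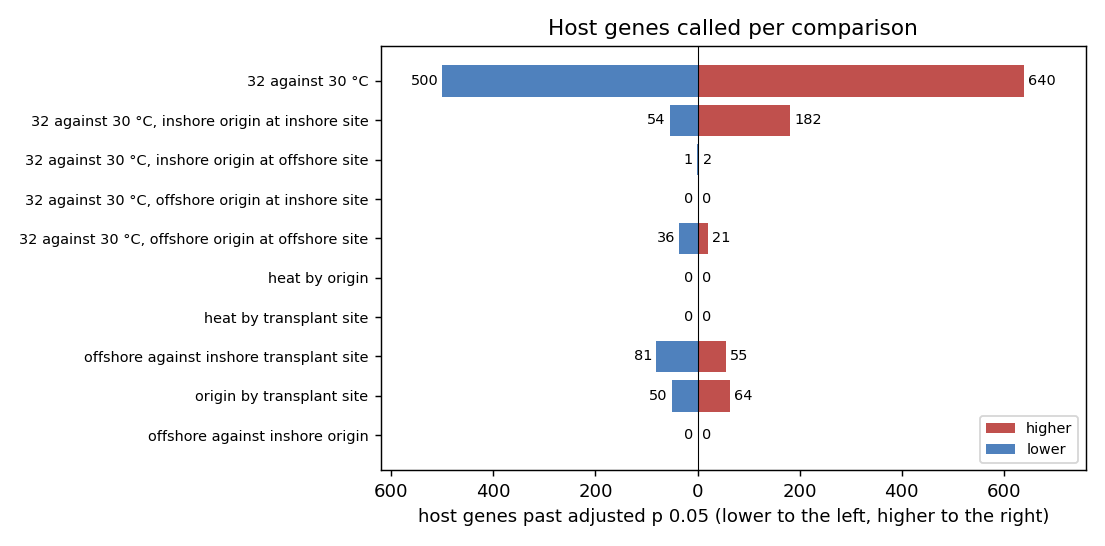
Numbers of host-table rows past an adjusted p of 0.05 in each comparison (edgeR, coral as block; origin on genotype sums), with lower rows as bars to the left of 0 and higher rows to the right. Reads of symbionts may be behind part of the rows called for transplant site and for origin by transplant site. Heat over all corals has the longest bars (500 lower, 640 higher), while heat in offshore-origin corals at the inshore site, heat by origin, heat by transplant site and origin have none.

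Within single combinations of origin and site, most heat calls were made in corals kept at the kind of site they came from. Inshore-origin corals at the inshore site had 182 genes higher and 54 lower at 32 °C (8 corals). Offshore-origin corals at the offshore site had 21 higher and 36 lower (6 corals). Inshore-origin corals at the offshore site had 3 genes past the threshold, and offshore-origin corals at the inshore site had 0 (edgeR; 1579 at an unadjusted p under 0.05, and 8 with DESeq2). These counts moved with the setting. DESeq2, run over 82742 genes without the low-count filter, called 543 and 312 genes in the first and second of these combinations and 78 in the third. With edgeR, leaving off that filter alone gave 171, 34 and 6. Leaving out the 7 libraries that stand apart gave 433, 339 and 31, and 3 in the last. In the first combination OFAVBQ_DN206490_c0_g1 rose 11.1-fold, from 1.70 ± 2.31 to 15.6 ± 13.2 CPM (SD, n = 8), and OFAVBQ_DN197500_c1_g1 rose 9.42-fold, both in 8 of 8 corals. OFAVBQ_DN200454_c0_g3 fell 13.7-fold and OFAVBQ_DN196565_c0_g1 fell 4.05-fold there, each in 7 of 8 corals. In offshore-origin corals at the offshore site OFAVBQ_DN212883_c3_g5 rose 16-fold, from 0.72 ± 0.391 to 25.7 ± 52.8 CPM (SD, n = 6). OFAVBQ_DN205365_c0_g2 rose 8.69-fold there, from 0.589 ± 0.52 to 6.8 ± 11 CPM (SD, n = 6). Each rose in 6 of 6 corals, but from low levels and with an SD at 32 °C above the mean, so the size of the rise was uneven between corals. In the same corals OFAVBQ_DN203101_c1_g1 fell from 43.4 ± 16.7 to 9.87 ± 1.72 CPM (SD, n = 6) in 6 of 6, and OFAVBQ_DN211751_c1_g2 fell from 771 ± 798 to 129 ± 79.8 CPM in 5 of 6. The 3 genes of inshore-origin corals at the offshore site were OFAVBQ_DN205365_c0_g1 (2.29-fold higher), OFAVBQ_DN203932_c4_g3 (1.71-fold higher) and OFAVBQ_DN207917_c2_g1 (1.70-fold lower), each in 8 of 8 corals.

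Most genes called in inshore-origin corals at the inshore site had the same sign in the other combinations, though few were called there. Of the 236 genes called in inshore-origin corals at the inshore site, 91.5% had the same sign in the same corals at the offshore site, 94.5% in offshore-origin corals at the inshore site and 85.6% in offshore-origin corals at the offshore site. Of the 236, 3, 0 and 5 were also called there. These combinations share no library. Over all 35219 genes the changes of any pair of combinations were weakly related (r across genes from 0.0863 to 0.228; genes are not independent replicates). The median change of the rising genes was log2 1.02 where they were called and 0.35, 0.46 and 0.36 in the other three, and part of that gap comes from the selection of the genes. Without the coral block 65, 0, 0 and 12 genes were called in the 4 combinations, in the order inshore origin at inshore and offshore sites, then offshore origin at inshore and offshore sites. Libraries numbered 17 to 56 alone gave 0 in each combination (edgeR; fewer libraries), against the 236, 3, 0 and 57 above. Calls in single combinations also rested on few corals: the 236 became 42 without B2, 45 without B4, 75 without A3, 82 without A5, 132 without B6, 152 without C4 and 693 without A6, and the 57 became 0 without C4 or C6, 11 without C2, 34 without A3, 88 without B4, 91 without A6 and 125 without C1. The 3 became 0 without A3, A5, A6, B3, B6, C4 or C6, 1 without B4 or C1 and 5 without C3, and the 0 became 1 without B3.

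A direct test of whether the heat response differs by origin found no gene (edgeR, 0 of 35219, with 1759 at an unadjusted p under 0.05). DESeq2, run over 82742 genes without the low-count filter, called 27. The test of heat by transplant site also found 0 (2057 at an unadjusted p under 0.05, and 25 with DESeq2). Within each origin, tests of heat by transplant site added after the data were seen called 0 genes for inshore-origin corals (edgeR; 1629 at an unadjusted p under 0.05) and 0 for offshore-origin corals (1334; DESeq2 not run for either). So no gene is shown to respond differently at the site of the same kind as the origin, and the difference between counts itself was not tested. The size of the response along the common direction had a mean slope of 0.374 ± 0.287 (SD) in the 6 offshore-origin genotypes and 0.443 ± 0.271 in the 6 inshore-origin genotypes (difference -0.070, exact permutation p = 0.673). The sign turned over the genes called for heat (0.097, exact permutation p = 0.552) and at the offshore site alone (0.061, p = 0.840, exact permutation), and at the inshore site alone the difference was -0.151 (exact permutation p = 0.498, 11 genotypes). For the 21 genes that heat raised in offshore-origin corals at the offshore site, no difference between origins in level at 30 °C at the inshore site was shown. Their median difference was 0.04 on the log2 scale (offshore minus inshore, exact permutation p = 0.686, 12 genotypes), with 10 of the 21 lower in offshore-origin corals, so genes went both ways. Among the 200 genes with the smallest p for a rise in the same corals, 87 were lower (median 0.04, exact permutation p = 0.429). Among 200 genes with the smallest p for a rise at the inshore site, a list chosen after the data were seen, 125 were lower in offshore-origin corals at the offshore site (median -0.072, exact permutation p = 0.416).

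Transplant site changed few rows of the host table, and those by large amounts. At the offshore site 55 rows were higher and 81 lower than at the inshore site (edgeR, coral as block). OFAVBQ_DN186005_c0_g2 and OFAVBQ_DN158100_c0_g1 were higher at the offshore site in 27 of 27 pairs (adjusted p = 6.75e-12 and 3.87e-12, edgeR). In offshore-origin corals at 30 °C OFAVBQ_DN158100_c0_g1 stood at 51.2 ± 17.4 CPM at the offshore site and 0.588 ± 1.08 at the inshore site (SD, n = 6). OFAVBQ_DN186005_c0_g1 and OFAVBQ_DN174110_c0_g2 were lower in 22 and 23 of 27 pairs. OFAVBQ_DN174110_c0_g2 stood at 46 ± 17.3 CPM in offshore-origin corals at the inshore site at 30 °C and at 0 in all 6 at the offshore site. With the log2 ratio of symbiont to host counts as a term beside the block, chosen after seeing the data, the fit called 43 rows, all 43 of them higher.

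The site difference depended on origin for 114 rows of the host table (64 higher and 50 lower in inshore-origin minus offshore-origin corals, edgeR). OFAVBQ_DN122952_c0_g1 is an example, with 0.192 ± 0.471 CPM at the inshore site and 32.0 ± 10.3 at the offshore site in offshore-origin corals at 30 °C (SD, n = 6), against 13.4 ± 9.31 and 30.4 ± 14.2 in inshore-origin corals (SD, n = 8). OFAVBQ_DN196190_c0_g1 and OFAVBQ_DN48895_c0_g1 went the other way, standing at 22.9 ± 7.93 and 25.9 ± 9.12 CPM in offshore-origin corals at the inshore site and at 0 in all 6 at the offshore site (30 °C, SD, n = 6). The fit without the block called 37 rows, libraries numbered 17 to 56 alone gave 0, and the fit with the symbiont ratio as a term gave 31, all 31 of them lower. Leaving out C4, B2, A6, C2 or C5 gave 49, 53, 57, 63 or 71. The balance of directions also moved. Without the block 2 rows were higher and 35 lower, and without C4, B2, A6, C2 or C5 14, 13, 17, 25 or 32 were higher and 35, 40, 40, 38 or 39 lower. RLE factors kept more higher than lower rows (64 and 51), as did DESeq2 (89 and 60).

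Offshore- and inshore-origin genotypes did not differ in any host gene past the threshold (edgeR on 6 against 6 genotype sums, 0 of 39603; 2038 at an unadjusted p under 0.05). DESeq2 called 152, and edgeR without genotype In1 called 2. Simulated 4-fold differences were recovered in 66.7% of genes at this size of design.

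Offshore-origin corals had a far higher symbiont share of counts at the inshore than at the offshore site. The share covers the D. trenchii table alone, so a low value does not show that a coral lacked other symbionts. Their share at the inshore site was 20.1% ± 5.46 (SD, n = 6) at 30 °C and 13.6% ± 7.69 (SD, n = 5) at 32 °C, and at the offshore site it was 0.133% ± 0.0440 and 0.513% ± 0.847 (SD, n = 6 each). The last value rests on C3, at 2.22% (Wilson 95% interval 2.21 to 2.23), and without it the mean was 0.171% ± 0.142 (SD, n = 5). Every one of the 6 corals had a lower ratio of symbiont to host counts at the offshore site, by 94.6-fold in C1 to 291-fold in C2. Their shares at the offshore site at 30 °C, 0.0792 to 0.184%, lay near those that B4 and B6 held in every condition, 0.0864 to 0.161%, so a floor common to these libraries is not excluded and the folds are best read as lower bounds. Within libraries numbered 17 to 56 the log2 change was -6.75 ± 0.851 (SD, 5 corals), against -7.24 ± 0.601 over all 6. The former rests on pairs at 32 °C alone, since no offshore-origin coral has both its 30 °C libraries in that range, while the latter uses both temperatures. Inshore-origin corals overlapped with these at the inshore site, with means of 6.78% ± 8.95 at 30 °C and 7.61% ± 8.52 at 32 °C, and 3.91% ± 8.73 and 4.07% ± 7.88 at the offshore site (SD, n = 8 each). These means rest on B2, and without it they were 4.29% ± 5.96, 5.63% ± 6.91, 0.878% ± 1.75 and 1.57% ± 3.73 in the same order (SD, n = 7 each). They varied between genotypes and also within In1. B2 held 21.5 to 25.1% at both sites, B4 and B6 held at most 0.161% anywhere, and of the 3 corals of genotype In1, A3 and A5 had ratios 55.9- and 38-fold lower at the offshore site while A6 was 1.03-fold lower. Over all 14 corals the log2 ratio of symbiont to host counts was 4.14 lower at the offshore site (-4.14 ± 3.39 SD, lower in 11 of 14 corals, exact sign-flip p = 0.00183, 0.00732 after Benjamini-Hochberg adjustment over 4 tests). Within origins, tested after the data were seen and adjusted over 9 tests, it was -7.24 in offshore-origin corals (6 of 6 lower, exact sign-flip p = 0.0312, the smallest that 6 corals allow, 0.141 adjusted). In inshore-origin corals it was -1.82 ± 2.60 (SD, n = 8, 5 of 8 lower, exact sign-flip p = 0.117, 0.281 adjusted) and -1.20 with In1 as 1 unit (exact sign-flip p = 0.250). So a site change is not shown for inshore-origin corals alone. The site change differed between origins (-6.04, offshore minus inshore origin, exact permutation p = 0.00217, the smallest that 6 against 6 genotypes allow, 0.0195 adjusted over 9 tests), a comparison added after the data were seen. B4 and B6 had little room to fall if such a floor holds, while A3 and A5 fell 55.9- and 38-fold. B2 and A6, also above that floor at the inshore site, hardly changed. At the inshore site alone the ratio was 4.22 higher in offshore-origin genotypes (log2), so starting share and origin are not separated here.

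A common shift of the share of the D. trenchii table with heat was not shown. The log2 ratio changed by 0.08 ± 1.36 (SD, n = 14) from 30 to 32 °C, upward in 6 of 14 corals (exact sign-flip p = 0.856), and by -0.21 without C3 or -0.05 without A6. This mean includes offshore-site libraries for which a floor is not excluded. It was -0.38 at the inshore site alone (9 of 13 corals lower, exact sign-flip p = 0.291) and 0.23 at the offshore site alone (5 of 14 higher, exact sign-flip p = 0.579). In offshore-origin corals at the inshore site, tested after the data were seen, it was -0.78 ± 0.910 (SD, n = 5). There 4 of 5 were lower (exact sign-flip p = 0.125, 0.281 adjusted over 9 tests). Neither the mean ratio (1.198 higher in offshore-origin genotypes, exact permutation p = 0.400) nor its heat change (0.61 higher, exact permutation p = 0.580) was shown to differ between origins. Both rest on single corals. Without B2 the mean ratio was 2.29 higher (exact permutation p = 0.0325). The heat change of C3 was 3.84, from the offshore site alone, and without C3 the difference in heat change was -0.09 (exact permutation p = 0.844). At the inshore site alone the ratio was 4.22 higher in offshore-origin genotypes (exact permutation p = 0.0260, 12 genotypes), and at the offshore site alone it was -1.51 (p = 0.327, exact permutation).

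**Figure D2:**
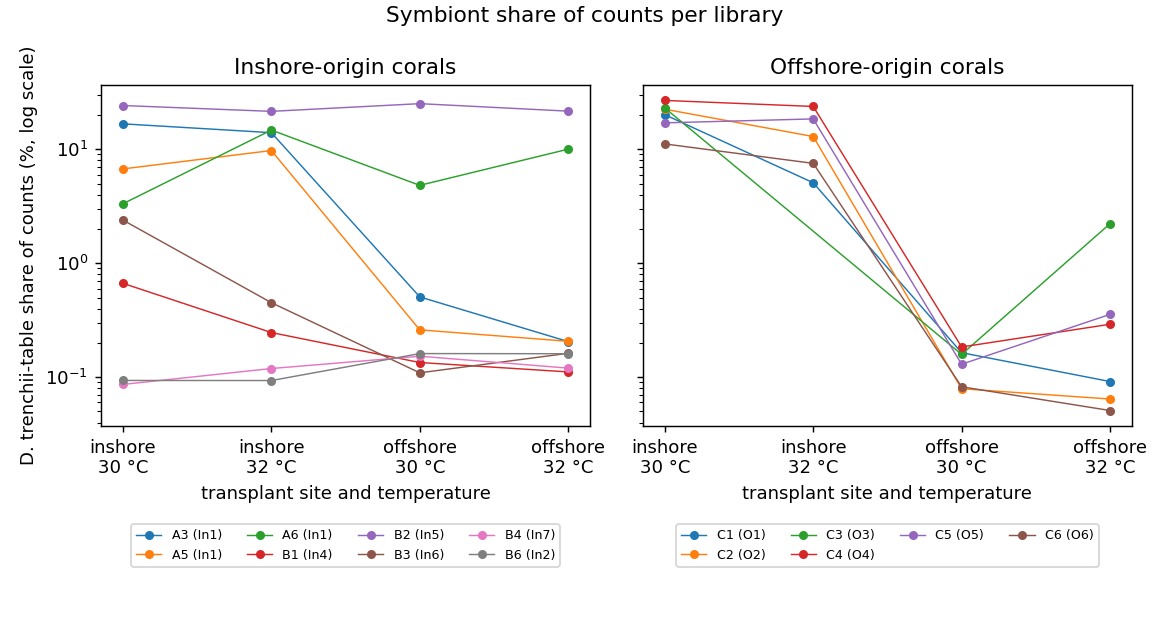
Share of counts in the D. trenchii table per library (percent, log scale) against transplant site and temperature, one line per coral with its genotype in brackets, inshore-origin corals on the left and offshore-origin corals on the right. C3 has no point at the inshore site at 32 °C. All 6 offshore-origin corals lie at 11.1% or above at the inshore site at 30 °C and at 0.184% or below at the offshore site at 30 °C.

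Within the symbiont table, transplant site separated most rows that could be tested. Of 288 rows, 140 were higher and 114 lower at the offshore site (edgeR, coral as block), and with RLE factors 60 were higher and 190 lower, since this scaling moved the median change of all rows from 0.38 to -1.47 on the log2 scale. Dtrenchii_DN306731_c0_g1 stood at 29700 ± 10400 CPM of the 288 tested symbiont rows in offshore-origin corals at the offshore site at 30 °C and at 20.1 ± 41.8 at the inshore site (SD, n = 6). Dtrenchii_DN151083_c0_g2 behaved alike, at 17700 ± 4450 and 10.1 ± 21 CPM. Both rows stood at 0 in all 5 offshore-origin libraries at the inshore site at 32 °C, which held 387754 to 1280078 symbiont counts. They were thus not detected where counts in the symbiont table were plentiful. Whether their reads come from D. trenchii was not tested, so their change is not shown to be a change in that symbiont. Dtrenchii_DN211305_c3_g3 went the other way, at 536 ± 880 CPM at the offshore site and 22800 ± 2020 at the inshore site, and Dtrenchii_DN210684_c0_g2 was at 0 in all 6 against 4310 ± 393. The offshore-site libraries behind these values held 4435 to 9261 symbiont counts in 369 to 2819 rows, with 5.42 to 10.4% of the counts in the top row. At the inshore site at 30 °C counts lay in 34909 to 39918 rows, with 0.579 to 0.702% in the top row. Site changes of single rows are therefore measured against libraries in which few rows were detected. The site change depended on origin for 167 rows, 67 higher and 100 lower in inshore-origin minus offshore-origin corals, and with RLE factors for 242, 187 higher and 55 lower. The lower ones included Dtrenchii_DN226373_c0_g1 and Dtrenchii_DN306731_c0_g1, and the higher ones Dtrenchii_DN210684_c0_g2 and Dtrenchii_DN212619_c0_g1. The balance of directions also depended on single corals and on which rows were tested. For site, 83 were higher and 65 lower without A6, 57 and 94 without B2, 103 and 66 without A3, 176 and 251 without B4, and 177 and 251 without B6. Libraries numbered 17 to 56 gave 68 higher and 139 lower. Over 50750 rows without the low-count filter, edgeR called 180 higher and 19056 lower, and DESeq2, also over 50750, called 60 and 27546. For origin by site, 20 were higher and 52 lower without B2, 36 and 63 without A6, 16 and 93 without C1, 11 and 99 without C6, and 153 and 131 without B4. Libraries numbered 17 to 56 gave 37, all 37 of them lower. Over 50750 rows edgeR called 16168 higher and 128 lower, and DESeq2 called 23687 and 56.

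No symbiont row passed the threshold for heat over all corals (edgeR, 0 of 288; 31 at an unadjusted p under 0.05, 0 with DESeq2, though 16 without the low-count filter, 14 higher and 2 lower), for heat by origin (0; 62, and 0 with DESeq2, though 34 without B4) or for heat by transplant site (0; 20, and 5 with DESeq2). In simulated symbiont data 0 of 5 heat changes of 1.5-fold were recovered over all corals, against 7 of 7 of 4-fold. That simulation gave all fragments of a coral the same composition, and 488 rows were tested in it against 288 here. Its recovery therefore does not carry over to these libraries, and neither small nor large heat changes are excluded. Between origins, 100 symbiont rows were lower and 6 higher in offshore-origin genotypes (edgeR on genotype sums, 22436 rows). These sums weight each library by its symbiont counts. At 30 °C offshore-origin libraries held 681583 to 1801987 at the inshore site and 4435 to 9261 at the offshore site. Libraries of In7 (B4) and In2 (B6) held 4470 to 8379 in every condition. So the calls for origin are not separated from the difference in symbiont counts between genotypes. Dtrenchii_DN143645_c0_g1 was among the lower ones, at 0 in all offshore-origin libraries at the inshore site against 2480 ± 3100 CPM in inshore-origin corals there at 30 °C (SD, n = 8). Dtrenchii_DN205109_c1_g6 was 86.7-fold lower in the summed counts, but at the offshore site at 30 °C it stood at 18800 ± 8150 CPM in offshore-origin (SD, n = 6) and 17000 ± 9610 in inshore-origin corals (SD, n = 8). Dtrenchii_DN218643_c2_g2 and Dtrenchii_DN301600_c0_g1 were 3.85- and 2.04-fold higher, and the former was -0.17 on the log2 scale with DESeq2. The higher direction depended on the setting. DESeq2 called 179, the fit without In7 called 64 and that without In2 called 65, all of them lower. Without the low-count filter 1 was higher and 101 lower, and without In5 15 were higher and 180 lower.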

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

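In this part, the comparison of host totals between temperatures was written down before its result was seen, and the other tests were chosen after their results or closely related values had been seen.

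Coral A6 of genotype In1 stood apart from the 7 other inshore-origin corals in the heat change of its symbiont to host ratio, at 1.73 on the log2 scale against -0.93 to 0.12. This was the 1 such gap in 30 sets of values tested, and chance flags about 1 set in 20. In A6 the share went from 3.33% to 14.7% at the inshore site, where its 30 °C library is among the 7 host libraries that stand apart (mean correlation 0.818), and from 4.82% to 10.02% at the offshore site.

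The effect of transplant site on the symbiont ratio differed between origins by -6.04 on the log2 scale. At the inshore site alone the ratio was 4.22 higher in offshore-origin genotypes (log2), so starting share and origin are not separated. Among offshore-origin corals the site change was -7.24 ± 0.601 (SD, n = 6). Host totals of these libraries differed by at most 1.91-fold, which argues against depth. Without the 20 largest symbiont rows the change was -7.37 ± 0.632, and within libraries numbered 17 to 56 it was -6.75 ± 0.851 (5 corals), which argue against a few dominant rows and against library number. The change between transplant sites was tested above, but what brings it about was not. A gain of D. trenchii at the inshore site or its loss at the offshore site may each give this pattern.

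The number of host-table rows whose site change depended on origin was 114, and for the symbiont table it was 167. To ask whether symbiont reads could be behind site rows of the host table, rows called in offshore-origin corals were followed in the 8 inshore-origin corals, which share no library with them. The median of the 79 rows lower at the offshore site changed in those corals as the symbiont ratio did (Pearson r = 0.975, exact permutation p = 0.000248, 0.000496 adjusted over 2 relations; Spearman rho = 0.922, exact p = 0.00258; r = 0.981 without the 2 corals farthest from the median; r = 0.944 over the 6 genotypes, exact p = 0.00833, 0.0167 adjusted, but rho = 0.812, exact p = 0.0722, since 3 of the 8 corals share In1), which is consistent with reads of D. trenchii in many of them but not in all: at the inshore site at 30 °C their median was 10.7 CPM in B2 and 0 in B4 and B6, while their sum was 2014 CPM in B2 and 1217 and 1967 in B4 and B6, and 3287 in C6 at the offshore site. The median of the 59 rows higher at the offshore site was higher there in 8 of 8 inshore-origin corals, though by log2 0.07 in A5. In B2, whose ratio hardly changed, it rose by log2 1.86, but near the floor. The B2 median was 0 CPM at the inshore site at both temperatures, and 0.855 (30 °C) and 1.3 (32 °C) at the offshore site. Over the 8 corals the change did not go against the ratio (Pearson r = 0.263, exact permutation p = 0.502, Spearman rho = 0.429, exact permutation p = 0.299, r = 0.537 without the 2 farthest). With the B2 rise near the floor, these values do not decide whether a further symbiont gives way to D. trenchii. Between these corals the level of the rows went against the ratio, with r = -0.85 at the offshore site (exact permutation p = 0.0029, 0.00397 adjusted over 4 relations, rho = -0.643, exact permutation p = 0.0962). That r was -0.501 without the 2 farthest corals, on which it rests. At the inshore site r was -0.486 (exact permutation p = 0.218, rho = -0.5, exact permutation p = 0.216, r = -0.654 without the 2 farthest). Sums of the rows were low at some high shares, at 156 to 241 CPM in B2 at both sites and 201 to 392 in offshore-origin corals at the inshore site. They were high at others, at 1004 in A3 at the inshore site at 30 °C (share 16.7%), 1569 in A5 there at 32 °C (9.75%) and 1644 in A6 at the offshore site at 32 °C (10.02%). Low sums also stood at low shares, at 477 in B4 at the inshore site (0.119%) and 525 in C6 at the offshore site (0.051%), both at 32 °C. That B4 library is among those that stand apart, and its pair at 30 °C was at 1338 CPM (share 0.0864%). The median of the rows rose by log2 0.07 (A5) to 1.89 (B4) in inshore-origin corals. In offshore-origin corals, where the rows were chosen, it rose by 2.265 (C3) to 4.772 (C1). So a site response of the same size in every coral is not shown. A further symbiont and a host response that differs between corals both stay open for the higher rows.

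Host calls for 32 against 30 °C were weighed against library number and depth. With a term for library numbers 1 to 16, the median log2 rise of the 640 rising genes was 0.47 against 0.45 without it, a ratio of 1.04, and that of the 500 falling genes was -0.52 against -0.53. All 640 and 499 of the 500 kept their sign, while 145 and 88 stayed past the threshold as the median standard error went from 0.107 to 0.151 and from 0.127 to 0.174. Host totals at 32 and 30 °C differed by 1.02-fold (exact sign-flip p = 0.672, 14 corals). Libraries numbered 17 to 56 alone, which are fewer, called 50 genes for heat and 0 in each single combination. The totals argue against depth. The kept sizes argue against library number as the main source, but the genes were chosen in the same libraries. Library number is thus not excluded for single genes, and a response to heat remains as a hypothesis.

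For each count taken singly, the splits give only whether chance in the assignment of samples is unlikely, with no allowance for the number of counts examined, and 1 is the smallest number of splits possible. Swapping temperatures within coral pairs, 1 of 40 splits, the real one, gave as many host genes as the 1140 for heat (highest other 50) and the 236 in inshore-origin corals at the inshore site (highest other 43), so chance is unlikely for each taken singly. The 57 in offshore-origin corals at the offshore site were also reached by the real split alone, but by a narrow margin (highest other 54), and the count fell to 0 without C4 or C6. The 3 genes in inshore-origin corals at the offshore site were reached by 3 of 40 splits, with a highest other of 10, so chance is not excluded there. Swapping sites or permuting origin, 1 of 40 splits gave as many as the 136 host rows for site (highest other 87), the 114 for origin by site (highest other 3) and the 167 symbiont rows for origin by site (highest other 118), so chance is unlikely for each taken singly. The margin was narrow for the 254 symbiont rows for site (1 of 40, highest other 241) and for the 106 symbiont rows between origins (1 of 60, highest other 98). Every split reaches a count of 0, so the 40 of 40 for host heat in offshore-origin corals at the inshore site (highest other 0), host heat by origin (3), host heat by site (397) and symbiont heat, heat by origin and heat by site (0 each), and the 60 of 60 for host origin (5), say nothing about chance. The 397 points to a structure of the samples, and its cause was not tested.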

How the results depend on the processing

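Alternatives that concern the symbiont ratio, the libraries that stand apart, corals left out of the share, the 200 inshore-site genes and the offshore-origin corals at the inshore site alone were chosen after seeing the data. The cause of each shift was not tested, except where fewer libraries are named. Other feature levels were not run because they are identical, gene lists were not tested, and the baseline list from the inshore site held no gene and gave no value.

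Host counts for transplant site (136) stayed between 125 (without A3) and 144 (without C2) when each coral was left out. With the symbiont ratio as a term the count was 43, and without the rows that go with that ratio it was 56. For origin by site (114) the values were 31 and 42 under those settings, 37 without the block, 0 in libraries 17 to 56 and 49 to 133 leaving out corals.

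Host counts for heat (1140) were 743 without the low-count filter, 321 without the block, 261 with the term for library number, 50 in libraries 17 to 56 (fewer libraries), 1751 without the libraries that stand apart and 655 to 1275 leaving out corals. For inshore-origin corals at the inshore site (236) they were 543 with DESeq2, 65 without the block, 0 in libraries 17 to 56, 433 without the libraries that stand apart and 42 to 693 leaving out corals. For inshore-origin corals at the offshore site (3) they were 78 with DESeq2, 6 without the filter, 31 without the libraries that stand apart, 5 with the symbiont ratio, and 0 without the block, with In1 summed, in libraries 17 to 56 and with the term for library number (0 to 5 leaving out corals). For offshore-origin corals at the inshore site (edgeR, 0; 1579 at an unadjusted p under 0.05) DESeq2 gave 8, and edgeR gave 3 without the libraries that stand apart and 0 to 1 leaving out corals. For offshore-origin corals at the offshore site (57) they were 312 with DESeq2, 34 without the filter, 12 without the block, 0 in libraries 17 to 56, 34 with the term for library number, 339 without the libraries that stand apart and 0 to 125 leaving out corals. DESeq2 called 27 for heat by origin, 25 for heat by site and 152 for origin, where edgeR called 0 (1759, 2057 and 2038 at an unadjusted p under 0.05). Leaving out corals kept both interactions at 0, and leaving out genotypes gave 0 to 2 for origin.

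Low depth limits the symbiont table, where 288 rows could be tested in all corals. Without the low-count filter 16 were called for heat, 19236 for site and 16296 for origin by site, and DESeq2 (also without that filter) gave 5 for heat by site, 27606 for site, 23743 for origin by site and 179 for origin. Site gave 167 with In1 summed, origin by site gave 37 in libraries 17 to 56, and heat gave 115 in offshore-origin corals at the inshore site alone, or 18 there with a term for library number. Leaving out corals or genotypes gave 148 to 428 for site, 72 to 284 for origin by site, 64 to 195 for origin, 0 to 34 for heat by origin and 60 to 99 for heat in those offshore-origin corals.

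The site change of the symbiont share kept its sign and its side of the threshold without the 20 largest rows and with In1 as 1 unit (-4.22 in both). At the inshore site alone the heat change was -0.38, its difference between origins -0.32, and the difference between origins 4.22, while at the offshore site alone the last was -1.51. Leaving out corals gave -4.52 to -3.83 for the site change of the share, -6.40 to -5.65 for its difference between origins, -0.21 (without C3) to 0.20 for the heat change, -0.090 (without C3) to 0.99 for heat by origin and 0.69 to 2.29 (without B2) for origin. The difference in the size of the heat response was 0.097 over called genes and 0.061 at the offshore site alone, and the baseline difference was -0.072 for the 200 inshore-site genes. Of 758 values of named identifiers under these settings, 624 kept direction and side of the threshold, 133 kept direction only, and 1 reversed, Dtrenchii_DN218643_c2_g2 between origins with DESeq2 (-0.17).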

Other observations

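The tests of heat in the symbiont within single combinations of origin and site, and of the offshore-origin corals at the inshore site alone, were chosen after the data were seen.

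In these 5 corals, whose libraries held 387748 to 1801984 symbiont counts, 60 symbiont rows were higher and 55 lower at 32 °C among 21259 tested (edgeR, coral as block). The median rise was 1.94-fold and the median fall 1.60-fold. Dtrenchii_DN162250_c0_g1 rose 5.11-fold, from 22 ± 23.4 to 93.2 ± 95.6 CPM of the symbiont rows tested there (SD, n = 5), in 4 of 5 corals, and Dtrenchii_DN208801_c0_g1 rose 3.25-fold in 4 of 5. Dtrenchii_DN201480_c0_g1 fell from 99.3 ± 7.38 to 32.3 ± 9.95 CPM (SD, n = 5) in 5 of 5 corals, and Dtrenchii_DN185295_c0_g1 fell 4.60-fold in 5 of 5. Without the block 121 rows were called, and leaving out C1 or C5 gave 60 or 62. Library number is nearly confounded with temperature here: 4 of the 5 libraries at 30 °C are numbered 1 to 16 and 0 of the 5 at 32 °C, so the pair from C2 alone separates them. With a term for library number the fit called 18 rows, among them 5 of the 60 and 2 of the 55, while 59 and 55 kept their sign. The median log2 rise of the 60 went from 0.96 to 0.73 and the median fall of the 55 from -0.68 to -0.67, and the median standard errors from 0.169 to 0.336 and from 0.139 to 0.296. So the change cannot be told apart from library number in the other 4 corals. The 16 splits that swap temperatures within corals are too few for a share under 0.05 (1 reached the real value of 115, and the highest other was 13). In the fit over all corals, where 288 rows could be tested, the same comparison called 0 (edgeR; 2 at an unadjusted p under 0.05, DESeq2 not run for it). That fit called 28 rows, all 28 higher at 32 °C, in offshore-origin corals at the offshore site, where C3 at 32 °C held 139512 symbiont counts and the other 11 libraries 2865 to 17415, and 0 in inshore-origin corals at either site (edgeR; 5 at an unadjusted p under 0.05 at each, DESeq2 not run). For these counts neither other splits nor other settings were run, so they are given as values alone. Whether this response differs from that of symbionts in other corals was not tested.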
